A study of Homo sapiens with 4 samples.

How the data were processed

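RNA was measured by bulk sequencing in 4 libraries of wild-type term placenta, 2 human and 2 mouse. Per the labels' protocols, total RNA was extracted with an RNeasy kit, ribosomal RNA was removed with Ribo-Zero, and libraries were made with the NEBNext Ultra Directional kit. Ribosomal depletion keeps transcripts without a poly(A) tail, among them replication-dependent histone mRNAs and small structural RNAs. The organism field of the labels names human for every sample, while the titles, the genome builds and the stated design name human and mouse. The titles were followed, and the gene symbols and coordinates of the 2 tables are those of human and mouse respectively. The replicate numbers come from the titles. The labels do not state whether replicates are separate donors or animals or which parts of the placenta were dissected, so p-values measure the spread between these libraries, which may be technical.

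The authors deposited raw counts of read pairs per gene, 1 table per species. Per the file headers, the counts were made with featureCounts 2.0.0 over exons grouped by gene name, counting pairs with both ends mapped, against Ensembl annotation of GRCh38 for human and GRCm38 for mouse. Per the submitters' processing notes, STAR, SAMtools and Subread were also used, and their versions are not given in the sources used here. Per the file headers, no strand option was set, so read pairs from a gene and its antisense partner were not told apart even though the kit keeps strand. No option for multi-mapping pairs or for pairs overlapping several genes was set either, and such pairs were not counted. Near-identical copies (CSH1 and CSH2, the CGB, PSG, haemoglobin and Prl families, clustered histone genes) and genes whose exons overlap those of another gene are therefore undercounted by an unknown amount. The tables also give each gene's exonic length in bases, per the file headers. No normalization was applied by the authors to the deposited counts. No column of per-sample values was left unused (0 columns).

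The human libraries held 25650366 and 17713596 counted pairs and the mouse libraries 37312638 and 28252484. A gene with no count in a library has an upper limit of 3 counts, and Poisson intervals at the 95% level are given for single counts. PCR duplicates were not marked by molecular identifiers, so intervals and limits cover counting error only. Replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 32.2 over 25724 genes in human and 37.6 over 18957 genes in mouse, and were kept as separate libraries. Genes of the Y chromosome, genes in the regions it shares with the X chromosome, XIST and TSIX were left out of every table for both species. CPM values use the deposited library totals.

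The human table lists 56048 genes and that of mouse lists 44236. Genes were matched between species by symbol regardless of case, plus listed aliases, which gave 16275 matched genes, 1 of them (HPRT1) through an alias. No table of orthologues and no mouse annotation beyond the deposited table was used here, so a shared symbol does not prove orthology (Ceacam and Prame genes, for example, belong to families that expanded separately). Of the matched genes, 15793 had at least 200 exonic bases in both species. Mitochondrially encoded genes were left out, and 13709 genes passed edgeR's filterByExpr. Human gene types and transcripts were taken from GENCODE 29 on GRCh38.

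The species were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts. The offset of each gene in each library was the log of its exonic length plus the log of the effective library size, which was set by TMM on length-scaled counts. P-values were adjusted by Benjamini-Hochberg over all 13709 genes, with a threshold of 0.05. Log2 fold changes are human over mouse with their standard error (SE). Abundance is the length-scaled CPM after TMM scaling, as mean ± SD of 2 libraries. Because a gene with no count in a species has no finite fold change, its ratio is given against a floor of 3 counts in each library, as a lower bound, unless exons of other genes cover more than a small part of it there, and genes with 1 to 3 counts are given with a counting interval.

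The 23 gene lists were tested with camera (limma 3.58.1) on the signed statistics with a preset inter-gene correlation of 0.01, and again with an estimated correlation, each adjusted over the 23 lists. Lists needed at least 5 tested members. The share of H2AJ among H2A transcripts was compared with an exact two-sided permutation test, for which the smallest possible p with 2 against 2 libraries is 0.333. Ranks of H2AJ and the most abundant unmatched genes, both by length-scaled count, were described without a test.

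The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes were H2AJ and the other listed histone variants, the 10 largest fold changes in each direction among called genes of at least 10 length-scaled CPM in the higher species with no overlap between the species' libraries, the 3 lowest adjusted p-values in each list, the 2 most abundant called genes of each called list, and the 10 most abundant unmatched genes of each species. The design was kept as fixed. Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, total scaling and housekeeping scaling, the DESeq2 Wald test, limma on log2(abundance + 0.5), no length term, no low-count filter or a mean of at least 50 counts, other gene sets, glmTreat against a 2-fold change, each library left out in turn and the replicate number as a block. After seeing the data, 4 more were added, namely 2 other lengths, protein-coding genes annotated on 1 sequence, and scaling to trophoblast epithelial genes. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

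The test was tried on simulated data between groups of the real sizes and depths. There 200 genes, drawn only from those above a minimum mean count, were changed by known folds, and a further gene list was moved together. The recovery given below therefore need not hold for genes with fewer counts. Every gene had the common dispersion of the data (0.033). In that simulation of the human versus mouse comparison on 13549 genes, edgeR recovered 58% of 2-fold and 100% of 4-fold changes, with 10 false calls among 192. Far fewer genes changed there than were called in the data, so the share of false calls need not hold in the real comparison.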

Results

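Term placenta of human and mouse was profiled by ribosome-depleted RNA sequencing, with 2 libraries per species. The stated purpose was to compare the counts of H2AJ, a replication-independent variant of histone H2A, between the species. The human libraries held 25650366 and 17713596 counted read pairs and the mouse libraries 37312638 and 28252484. Abundance is given as length-scaled CPM after scaling between the libraries. The first principal component of 13709 matched genes separated the species and held 96.5% of the variance, and the second, with 2.44%, separated the human libraries from each other. Across genes, log2 CPM of replicates correlated with r = 0.982 in human and 0.993 in mouse, over genes that are not independent replicates. The signal recognition particle RNA RN7SL2 was the most counted gene in human (4.33% and 4.0% of counts), and the transcription regulator RN7SK in mouse (2.79% and 2.83%).

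H2AJ was higher in human than in mouse placenta, at 78.2 ± 8.72 against 57.7 ± 1.58 length-scaled CPM (SD, n = 2 each). The difference was 1.36-fold, with a log2 fold change of 0.44 (SE 0.14) and an adjusted p of 0.0255 in edgeR's quasi-likelihood test, and both human libraries lay above both mouse libraries. In the human table the gene is H2AFJ on GRCh38 chromosome 12, from 14774383 to 14778002 on the plus strand, with 3356 exonic bases. Its protein-coding transcript in GENCODE 29 is a single exon of 644 bases ending at 14775026, with the coding sequence at 14774471 to 14774857, and 2 further transcripts annotated as targets of nonsense-mediated decay supply the other exonic bases. In the mouse table H2afj is a single exon of 1827 bases on GRCm38 chromosome 6, from 136808244 to 136810070 on the plus strand, of which 141 bases also belong to the antisense gene AC122804.1. Raw counts were 1366 (95% Poisson interval 1294 to 1441) and 1155 (1089 to 1224) in the human libraries and 968 (907 to 1031) and 822 (766 to 881) in the mouse libraries, or 53.3 and 65.2 CPM against 25.9 and 29.1 CPM. The call was lost without human library 2 (log2 fold change 0.32), without mouse library 1 (0.41), without mouse library 2 (0.46), with trophoblast epithelial scaling (0.23) and with length taken over bases free of other genes (0.29), while adjusted p over the alternatives ran from 2.37e-05 to 1, the latter against a 2-fold change. The value itself depended on scaling and length, being 1.21 with total scaling, 1.32 with housekeeping scaling, 1.0 with no length term and 2.82 with the human coding exon alone as length. That last setting shortened the human length only, while the mouse length stayed at 1827 bases and the counts were unchanged.

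**Figure D1:**
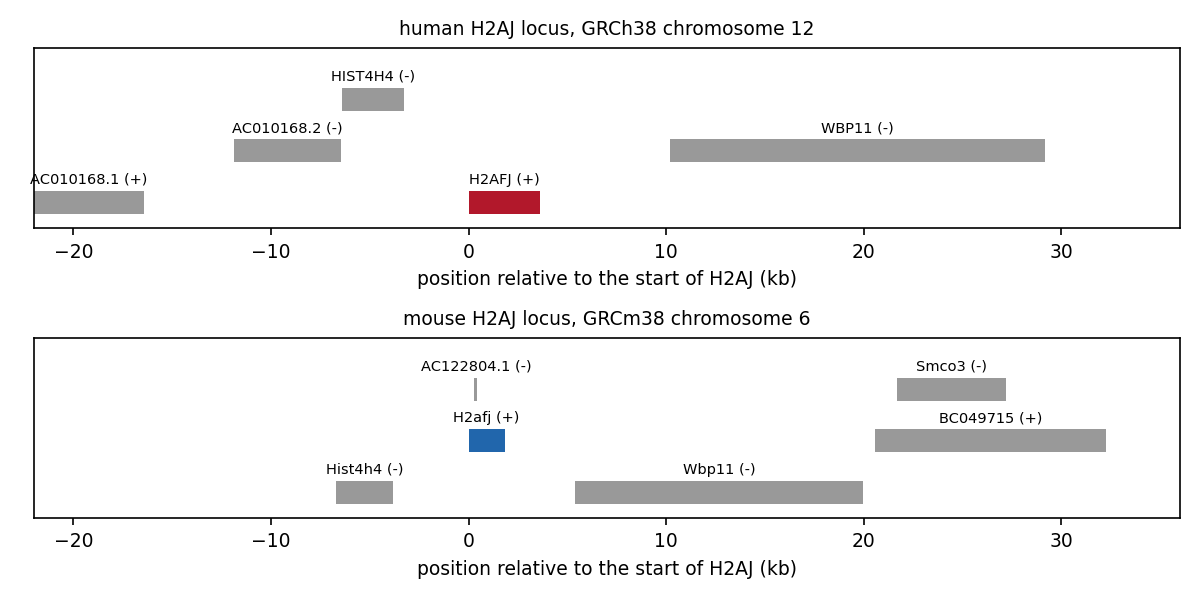
Genes around H2AJ drawn to scale from the deposited coordinates, human on GRCh38 chromosome 12 (top) and mouse on GRCm38 chromosome 6 (bottom), with position in kb from the start of H2AJ on the horizontal axis and the strand in parentheses. H2AJ (coloured) lies between HIST4H4 and WBP11 in both species, and the mouse gene contains the 141-base AC122804.1.

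**Figure D2:**
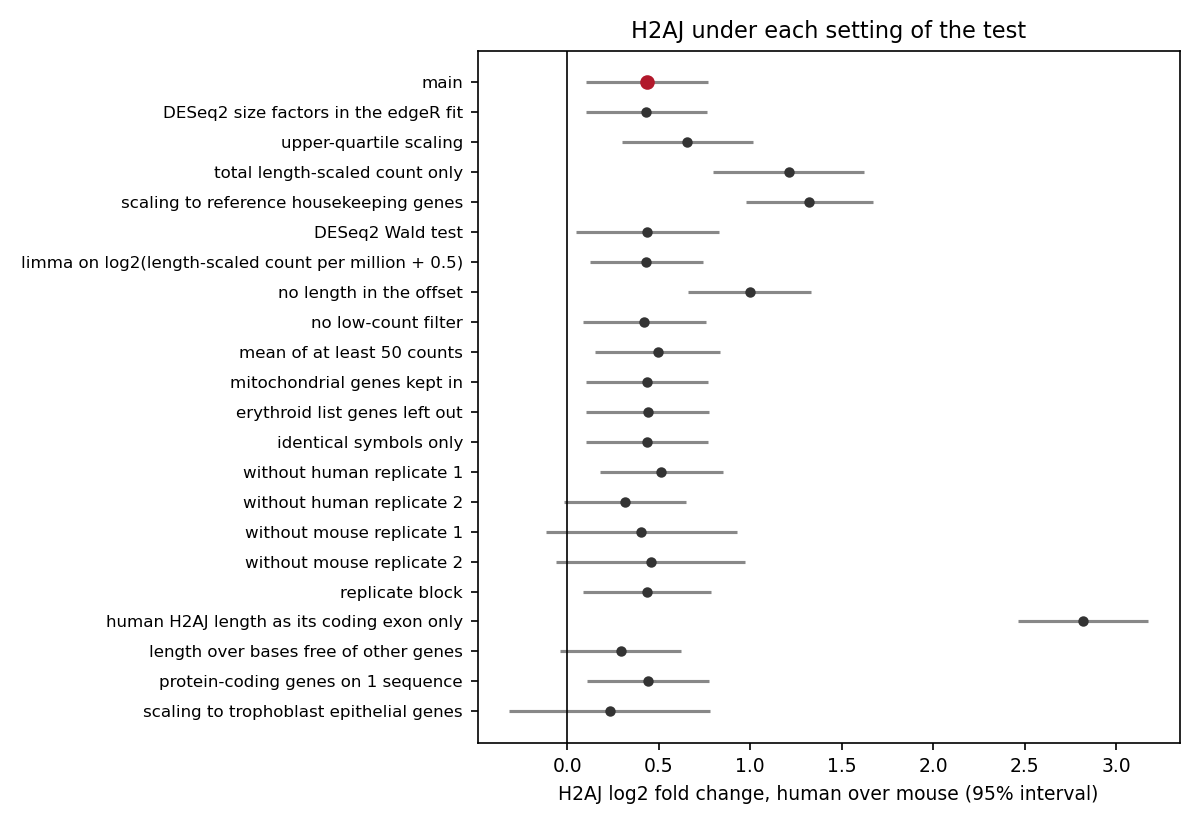
Log2 fold change of H2AJ, human over mouse, on the horizontal axis, with its 95% interval, for the reported fit (red, marked main) and each alternative with an interval (black). Point values run from 0.23 to 2.82, the latter with only the human length shortened. The interval includes 0 when human library 2, mouse library 1 or mouse library 2 is left out, with free bases as length and with trophoblast epithelial scaling.

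The part of all H2A transcripts formed by H2AJ depended on the length assigned to the human gene, and replication-dependent H2A genes, which are transcribed in S phase, formed a larger part in human. With all annotated exons as length, H2AJ was 2.53% ± 0.052 of H2A transcripts in human and 4.18% ± 0.55 in mouse (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). With the human coding exon alone as length the order was reversed, at 11.9% ± 0.22 in human and 4.18% ± 0.55 in mouse (n = 2 each, exact permutation p = 0.333). Only the human length was shortened there. The mouse length and the counts of both species were unchanged, so these shares are unlike measures. With all annotated exons, replication-dependent genes made up 90.4% and 91.7% of H2A transcripts in the human libraries and 73.3% and 70.3% in the mouse libraries. Their summed abundance was 2812 ± 284 length-scaled CPM in human and 999 ± 134 in mouse, 2.81-fold higher in human, and 2.45- to 5.19-fold higher under the other scalings. Among replication-independent H2A genes alone the order was the other way, with H2AJ at 28.4% ± 3.54 in human and 14.8% ± 0.85 in mouse (n = 2 each, exact permutation p = 0.333). By raw counts the share in the whole family was 8.13% ± 0.048 and 8.30% ± 0.73 (n = 2 each, exact permutation p = 1.0), a difference smaller than the spread between libraries. Near-identical clustered H2A genes, several of them with no count, are undercounted because multi-mapping pairs were not counted. Within each library, H2AJ ranked 2169th of 31872 and 1707th of 33151 genes with a count in human (top 6.81% and 5.15%), and 3402nd of 23897 and 3184th of 23454 in mouse (top 14.2% and 13.6%).

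Other histone variants differed in both directions. Of 11 replication-independent variants, 3 were higher in human, 4 were higher in mouse and 4 were not called. The linker histone H1-10 was 32.5-fold higher in human (114 ± 3.17 against 3.50 ± 0.39 length-scaled CPM, adjusted p 1.36e-05), and H3-3A, which encodes the H3.3 protein, 2.72-fold. The linker histone H1-0 was 2.97-fold higher in mouse and H2AX, the variant phosphorylated at DNA breaks, 2.56-fold, but the H2AX call was lost with housekeeping scaling (log2 fold change -0.47, adjusted p 0.0639). H2AZ1 was 1.82-fold and H3-3B 1.39-fold higher in mouse. The direction of H2AZ1 turned with housekeeping scaling, and its call was lost with total scaling (-0.10). The direction of H3-3B turned with total scaling, housekeeping scaling and no length term, and its call was lost with upper-quartile scaling (-0.26) and without mouse library 1 (-0.45) or 2 (-0.51). CENPA, the centromeric H3, had a log2 fold change of 0.95 (adjusted p 0.0748), which passed the threshold without human library 1 (1.18), with upper-quartile (1.17), total (1.73) and housekeeping scaling (1.83), and with limma (0.78). H2AZ2 had -0.30 (adjusted p 0.0749), and was called higher in mouse without human library 1 (-0.41) but higher in human with total scaling (0.46), housekeeping scaling (0.59) and no length term (0.93). MACROH2A1 had 0.01 (adjusted p 0.967) and was called higher in human with total scaling (0.78), housekeeping scaling (0.89), no length term (1.07) and free bases as length (0.51). MACROH2A2 had -0.64 (adjusted p 0.16) and was called higher in mouse with no length term (-1.09). As a list the variants were not called (camera adjusted p 0.84), and their median of -0.30 ran from -0.53 to 0.59 over the scalings. Histone chaperones and remodellers were split, with 5 of 19 higher in human, 8 higher in mouse and 6 not called (camera adjusted p 0.741). Among them the H3-H4 chaperone NASP was 3.87-fold and the remodeller ATRX 2.39-fold higher in human, and HJURP, the chaperone of CENPA, was 5.41-fold higher in mouse.

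**Figure D3:**
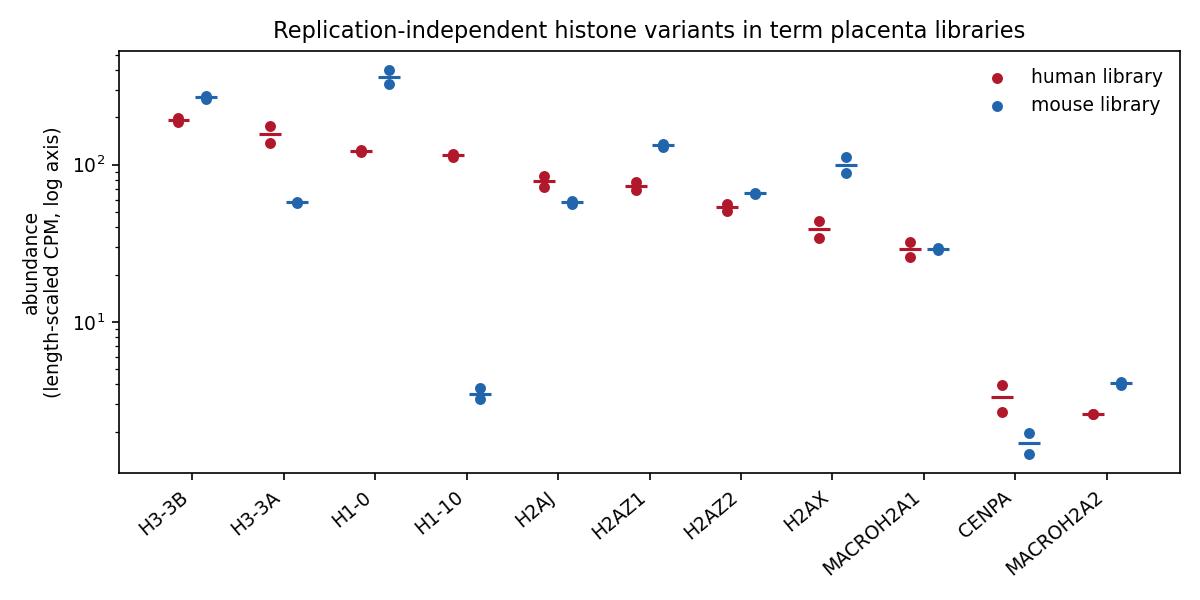
Abundance of the 11 replication-independent histone variants (length-scaled CPM, log axis), each point a library and each line the mean of 2 libraries, human in red and mouse in blue. H2AJ lies at 78.2 length-scaled CPM in human and 57.7 in mouse, while H1-10 lies at 114 and 3.50.

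Over all matched genes, 10420 of 13709 passed an adjusted p of 0.05, with 5232 higher in human and 5188 higher in mouse. Total scaling gave 7347 and 3295 and housekeeping scaling 7786 and 3128, and these scalings moved the median log2 fold change of all genes from 0.01 to 0.77 and 0.89. RN7SK and RPPH1 entered the mouse totals at 325419 and 126322 length-scaled CPM but had no count in human. There 0% of their exonic bases were free of other genes' exons, so part of the shift with total scaling may come from uncounted pairs. How much was not tested. Upper-quartile scaling gave 5809 and 4571, with a median of 0.22, and trophoblast epithelial scaling 4275 and 5381, with a median of -0.22. Against a 2-fold change, 3310 genes were called higher in human and 3268 in mouse. Folds rest on annotated exonic lengths, which differ widely between the species for some named genes. EED has 7016 bases in human and 2218 in mouse, and KLRD1 17404 and 1281. With no length term, 82.7% of calls were kept with the same sign, and 263 genes were called in the other direction.

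The 10 largest differences toward human included 3 hormone genes, aromatase and complement genes. KISS1, which encodes kisspeptin, had 55763 and 26884 counts in human and none in mouse, where only 21.3% of its exonic bases were free of other genes' exons. CGA, the shared alpha subunit of glycoprotein hormones, had 56898 and 36081 counts in human and none in mouse, with 68.0% of its mouse exonic bases free. No bound is given for either ratio, since pairs over shared bases were not counted. CRH, corticotropin-releasing hormone, was at least 2709-fold higher. CYP19A1, the aromatase that makes oestrogens, was at 4425 ± 486 length-scaled CPM in human and had 1 count in mouse, a ratio of 196800 (95% counting interval 35320 to 7772000). Complement component C7 was at least 3528-fold higher and the macrophage complement receptor VSIG4 at least 523-fold. NLRP2 and MAGEA10 (at least 691- and 422-fold) also had no count in mouse. SOWAHC had none either, but 0.11% of its mouse exonic bases were free, so its ratio is unknown. The entry 7SK, also with no count in mouse, names the same RNA as RN7SK, which had 1039297 and 799887 counts in mouse, so neither entry gives a species difference. Toward mouse, AFP, the fetal serum protein alpha-fetoprotein, had 252670 and 282379 counts in mouse and 2 in human, a ratio of 126000 (95% counting interval 34890 to 1041000). The growth hormone-releasing hormone gene GHRH was at least 906-fold higher in mouse, PRAMEF12 at least 1268-fold, and CEACAM5 was at 4626 ± 930 against 0.17 ± 0.17 length-scaled CPM. Coagulation factor F11 had 3260 and 2530 counts in mouse and none in human, where 89.5% of its exonic bases were free. RN7SK, RPPH1, SCARNA2, EEF1G and CD68 had no count in human, where 0%, 0%, 0%, 0.07% and 14.2% of their exonic bases were free of other genes, and pairs over shared bases were not counted.

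Of 25 tested syncytiotrophoblast and secreted factors, 19 were higher in human, 2 were higher in mouse and 4 were not called (camera adjusted p 0.000458; adjusted p = 0.674 with an estimated correlation). The stress cytokine GDF15 was 1217-fold higher in human (3284 ± 986 length-scaled CPM), CAPN6 153-fold, and the protease inhibitor TFPI2 5.64-fold (10510 ± 2034 length-scaled CPM). The 2 members higher in mouse were HTRA3 (25.4-fold) and the RNA-binding protein gene IGF2BP1 (3.21-fold). In human, 15 of 25 members were higher in library 1 (median log2 ratio 0.26). The list names 47 genes, 25 of them tested, and mouse placental families without a symbol match could not enter. Its direction therefore depends in part on how the list was composed. Of 10 tested mouse trophoblast lineage genes, 7 were higher in mouse, 1 was higher in human and 2 were not called (camera adjusted p 0.0202; adjusted p = 0.898 with an estimated correlation). The gap junction genes GJB2 and GJB3 were 3933- and 46.1-fold higher in mouse, the transcriptional regulator CITED2 10.1-fold, and CITED1 had 3 counts in human against 7668 and 4925 in mouse, a ratio of 1994 (95% counting interval 682 to 9671). GJB2 had 3 and 2 counts in human, so the size of its fold is uncertain. The member higher in human was PLAC1 (13.9-fold). In mouse, 10 of 10 members were higher in library 1 (median log2 ratio 0.53). Only 10 of the 50 genes named in this list were tested, and its direction likewise depends in part on its composition. Of 31 trophoblast transcription factors, 19 were higher in human, 7 were higher in mouse and 5 were not called (camera adjusted p 0.04999; adjusted p = 0.898 with an estimated correlation). That list kept its call in 11 of 22 alternatives, with adjusted p from 0.00192 to 0.218, and lost it without mouse library 2 (0.0666). Its median log2 fold change of 1.25 lay between 1.08 and 2.13 where the call was lost. ESRRG was 241-fold, TFAP2A 19.5-fold, TBX3 18.5-fold and the cofactor VGLL3 9.84-fold higher in human. Among the 7 higher in mouse, HAND1 had no count in human and was at least 440-fold higher, and TEAD4 was 7.35-fold higher. Extravillous trophoblast genes had 10 of 21 members higher in human, 4 higher in mouse and 7 not called (camera adjusted p 0.438), with the protease ADAM12 175-fold and ERBB2 14.0-fold higher in human and PLAC8 14.2-fold higher in mouse. This list also separated the human libraries, with 19 of 21 members higher in library 1 and a median log2 ratio of 0.69. Trophoblast epithelial genes were split, with 10 of 20 higher in human, 7 higher in mouse and 3 not called (camera adjusted p 0.741), ITGB4 being 14.6-fold higher in human, and EPCAM 41.3-fold and FGFR2 8.51-fold higher in mouse.

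Steroid and transport genes also went in both directions. Of 18 steroid genes, 6 were higher in human, 10 were higher in mouse and 2 were not called (camera adjusted p 0.488). HSD11B2, which inactivates cortisol, was 109-fold higher in human, and CYP17A1, which makes androgens, was 359-fold higher in mouse, opposite to CYP19A1. Of 31 nutrient and ion transport genes, 11 were higher in human, 16 were higher in mouse and 4 were not called (camera adjusted p 0.438), and their median of -0.42 turned to as high as 0.46 over the scalings. The calcium-binding protein S100G was 3390-fold (4750 ± 1159 length-scaled CPM) and the amino acid transporter SLC38A4 252-fold higher in mouse, while the calcium channel TRPV6 was 8.24-fold higher in human. With 2 and 4 counts of S100G and 6 and 5 of CYP17A1 in human, the sizes of these folds are uncertain. Of 32 imprinted genes, 14 were higher in human, 13 were higher in mouse and 5 were not called (camera adjusted p 0.92), with ZFAT 29.3-fold higher in human and GRB10 13.9-fold higher in mouse.

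Most tested markers of vessels and macrophages were called higher in human. Of 20 endothelial markers, 16 were higher in human, 3 were higher in mouse and 1 was not called (camera adjusted p 0.00961; adjusted p = 0.674 with an estimated correlation). The nitric oxide synthase NOS3 was 54.9-fold, MMRN2 11.3-fold, EGFL7 10.4-fold, PECAM1 2.83-fold and ESAM 2.18-fold higher in human, while EMCN (30.2-fold) and PLVAP (2.72-fold) were among those higher in mouse. EMCN had 4 and 18 counts in human, so the size of its fold is uncertain. Of 18 macrophage and myeloid markers, 13 were higher in human, 2 were higher in mouse and 3 were not called (camera adjusted p 0.0202; adjusted p = 0.898 with an estimated correlation), a call lost with total scaling (adjusted p 0.109) and housekeeping scaling (0.134), within a range from 0.00185 to 0.134. The median log2 fold change of the list was 2.86, and 3.62 and 3.75 where the call was lost. In mouse, 17 of 18 members were higher in library 2 (median log2 ratio of library 1 over 2 of -0.64). AIF1 was 22.6-fold and S100A9 22.1-fold higher in human. The 2 higher in mouse were S100A8 (6.09-fold, at 50.1 ± 29.1 length-scaled CPM in human) and CD68, whose human exons are mostly shared with other genes. HAND1, TEAD4, HTRA3, IGF2BP1, PLAC1, EMCN, PLVAP and S100A8 were chosen after their values were seen. Stromal and smooth muscle markers were split, with 12 of 22 higher in human, 7 higher in mouse and 3 not called (camera adjusted p 0.331). EGFL6 was 441-fold and NOTCH3 17.2-fold higher in human, and desmin (DES) was 10.7-fold higher in mouse. Lymphoid and NK markers had 5 of 15 members higher in human, 3 higher in mouse and 7 not called (camera adjusted p 0.741), with CD4 268-fold and KLRD1 34.9-fold higher in human and NCAM1 257-fold higher in mouse. These folds rest on few counts in the lower species, namely 2 and 7 for CD4, 4 and 5 for KLRD1 and 2 and 13 for NCAM1. Of 14 erythroid genes, 7 were higher in human, 2 were higher in mouse and 5 were not called (camera adjusted p 0.331), with BPGM, which makes 2,3-bisphosphoglycerate, 24.9-fold, SPTB 8.62-fold and TAL1 3.84-fold higher in human. The human libraries stood apart in this list, with 0 of 14 members higher in library 1 and a median log2 ratio of -1.53, and haemoglobins took 0.0722% and 0.433% of their counts against 0.764% and 0.775% in mouse.

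Yolk sac and endoderm genes were higher in mouse in 17 of 20 cases, higher in human in 2 and not called in 1 (camera adjusted p 0.000458; adjusted p = 0.674 with an estimated correlation). The median log2 fold change was -7.14, or -6.38 with genes at 3 counts or fewer set to their bound or ratio. In mouse, 14 of 20 members were higher in library 2 (median log2 ratio of library 1 over 2 of -0.27). The apolipoprotein APOA1 was 2517-fold higher in mouse (4019 ± 1303 against 1.56 ± 0.26 length-scaled CPM), and APOA2 had 1 count in human against 3080 and 2792 in mouse, a ratio of 4978 (894 to 196600). Of 20 decidual markers, 12 were higher in mouse, 6 were higher in human and 2 were not called (camera adjusted p 0.0928, and 0.0236 without mouse library 1, within a range from 0.00611 to 0.268). In mouse, 18 of 20 members were higher in library 2 (median log2 ratio of library 1 over 2 of -0.42). SFRP5, an inhibitor of Wnt signalling, was 378-fold and IGFBP2 27.6-fold higher in mouse. SFRP5 had 11 and 4 counts in human, so the size of its fold is uncertain.

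Cell cycle genes were higher in human in 26 of 30 cases, higher in mouse in 1 and not called in 3 (camera adjusted p 0.000458; adjusted p = 0.898 with an estimated correlation). The topoisomerase TOP2A was 8.67-fold and the replication helicase subunit MCM3 6.93-fold higher in human, and PCNA 1.51-fold, which turned to a log2 fold change of -0.43 with no length term and lost its call without mouse library 1 (0.56) and with trophoblast epithelial scaling (0.38). RRM2, a subunit of the reductase that makes deoxyribonucleotides, was 25.4-fold higher in mouse. The list also separated the human libraries, with 22 of 30 members higher in library 1 and a median log2 ratio of 0.23. Hypoxia and glycolysis genes were higher in mouse in 16 of 23 cases, higher in human in 4 and not called in 3 (camera adjusted p 0.0202; adjusted p = 0.898 with an estimated correlation). The angiogenic factor VEGFA was 41.5-fold, hexokinase HK2 22.6-fold, BNIP3 11.9-fold and the glycolytic enzyme ALDOA 4.03-fold higher in mouse, and the hypoxia-inducible factor EPAS1 was 3.89-fold higher in human. Total scaling, housekeeping scaling and no length term ended this call (adjusted p 0.0543, 0.0748 and 0.0617, in a range from 0.00747 to 0.0748). The median log2 fold change of the list, -0.91, shrank to -0.15 and -0.03 with these scalings and was -1.0 with no length term. In human, 21 of 23 members were higher in library 1 (median log2 ratio 0.29).

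Senescence and secretory genes had 13 of 25 members higher in human, 9 higher in mouse and 3 not called (camera adjusted p 0.575), with IGFBP4 9.17-fold higher in human and PLAUR 36-fold higher in mouse. Interferon-stimulated genes had 9 of 27 higher in human, 7 higher in mouse and 11 not called (camera adjusted p 0.945), with OAS3 9.89-fold higher in human, and ISG20 26.6-fold and USP18 15.9-fold higher in mouse. This list also separated the human libraries, with 0 of 27 members higher in library 1 and a median log2 ratio of -0.64. DNA methylation and Polycomb genes had 4 of 20 higher in human, 7 higher in mouse and 9 not called (camera adjusted p 0.741), with the demethylase TET2 6.13-fold higher in human, and CBX7 8.88-fold and EED 4.54-fold higher in mouse. Reference housekeeping genes also differed, with 8 of 27 higher in human, 14 higher in mouse and 5 not called (camera adjusted p 0.554), among them HPRT1 21.6-fold and HMBS 12.9-fold higher in mouse and SNRPD3 7.19-fold higher in human. With an estimated correlation camera called 0 of 23 lists at an adjusted p of 0.05, and 1, the syncytiotrophoblast list, had an unadjusted p under 0.05 (0.0478). Counts of called members adjusted over the list alone were equal to those given, except that 3 yolk sac genes were then higher in human and 6 DNA methylation and Polycomb genes higher in mouse.

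**Figure D4:**
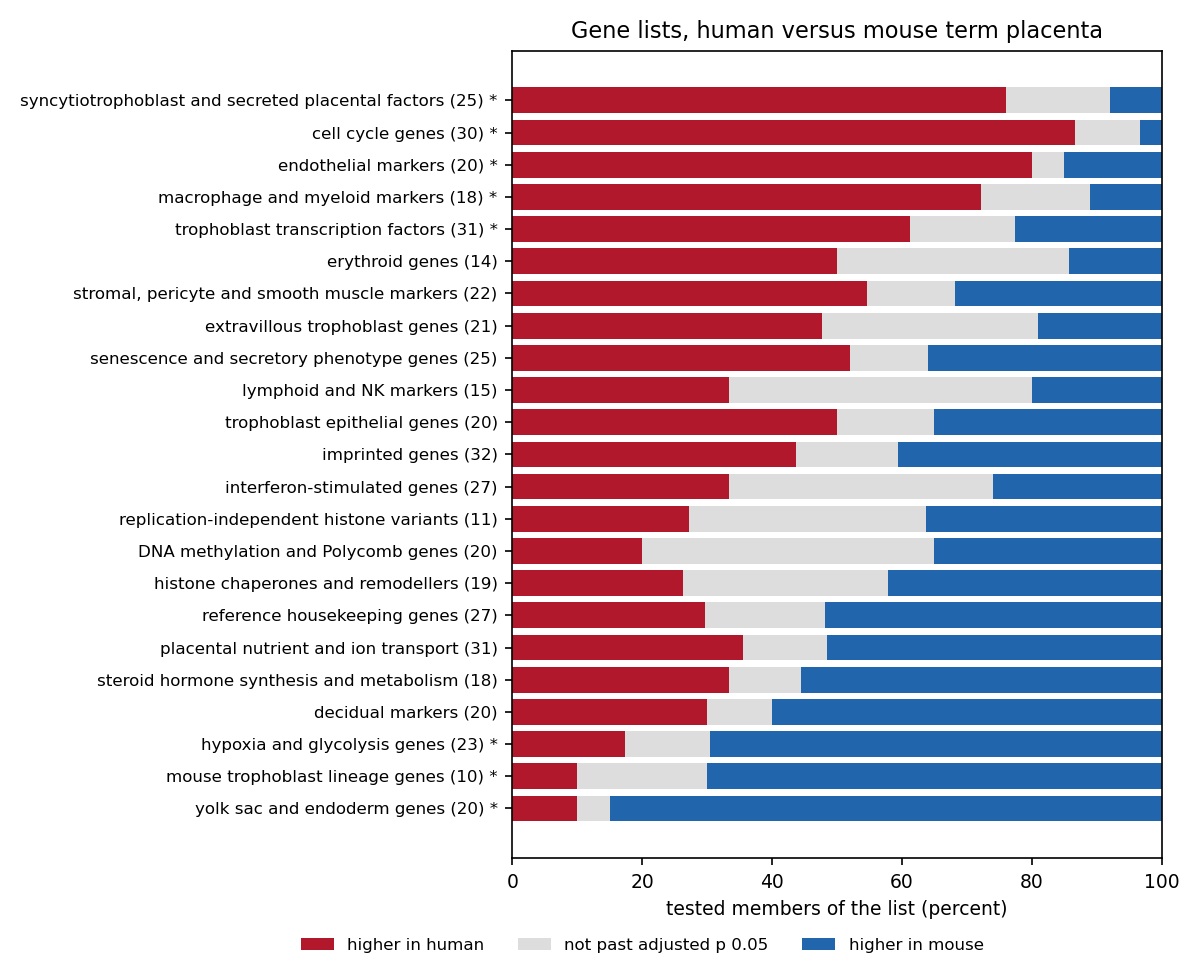
Share of tested members of each gene list (percent, horizontal axis) called higher in human (red), higher in mouse (blue) or not past an adjusted p of 0.05 (grey), with the number tested in parentheses and an asterisk where camera with the preset correlation called the list. Cell cycle genes have 26 of 30 members higher in human, and yolk sac and endoderm genes 17 of 20 higher in mouse; no list was called with an estimated correlation.

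Genes without a symbol match included placental hormone families of each species. In human, after RN7SL2, these were the placental lactogens CSH1 (28240 ± 756 CPM, n = 2) and CSH2 (10022 ± 527), on GRCh38 chromosome 17, and the pregnancy-specific glycoproteins PSG4 (6593 ± 983), PSG1 (4568 ± 277), PSG3 (3191 ± 610) and PSG2 (2810 ± 648), on chromosome 19. The beta-globin HBB (329 and 2030 CPM in the human libraries), AL773572.1 (1226 ± 302) and the small Cajal body RNA SCARNA7 (279 ± 23.1) completed the list. In mouse, the placental lactogen Prl3b1 stood at 11538 ± 936 CPM, Tpbpa at 13038 ± 2448 and Tpbpb at 8013 ± 1690, and the placental cathepsins Ctsj at 11322 ± 1394 and Ctsq at 7740 ± 18.3, all on GRCm38 chromosome 13. Ceacam11 (7201 ± 2102), Prl8a9 (5243 ± 841), Prl8a6 (5712 ± 230), Psg23 (10334 ± 1471) and Hbb-bs (3888 ± 23.0) were the others. These 10 genes per species were ranked by length-scaled count, while the values given are CPM. Longer genes outside them can therefore exceed those listed, such as mouse Psg16 (14546.5 ± 2464 CPM) and human ALPP (1830 ± 50.7 CPM). As families, the lactogen and growth hormone genes took 3.97% ± 0.051 of human counts, and the mouse Prl genes 3.29% ± 0.38 of mouse counts. Pregnancy-specific glycoproteins took 2.34% ± 0.25 in human and 4.86% ± 0.91 in mouse (n = 2 each). Reads of near-identical members may be split or lost, so values of single members are uncertain.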

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

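The tests of explanations in this part were chosen after the results they bear on were seen. Mitochondrially encoded genes lay outside the comparison of species and carried a signal above the limit of a zero count, with 0.21% and 0.269% of counts in the human libraries and 0.252% and 0.284% in the mouse libraries.

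A first pattern is that 50 matched genes had 3 counts or fewer in one species and at least 2000 in the other, 38 of them low in human and 12 low in mouse. For 10 of these (20%), including human CD68, EEF1G, RN7SK, RPPH1 and SCARNA2 and mouse KISS1 and SOWAHC, under 50% of exonic bases were free of other genes' exons, against 1.06% of all 9071 cases of a gene with that many counts in the other species (Fisher's exact test, one-sided, p = 7.92e-11). For these genes, loss of read pairs that overlapped several genes is a candidate explanation for the low count. The same loss is argued against for 36 genes with at least 90% of their bases free, among them AFP, CRH, C7 and GHRH. For those, differences between the species in expression, or symbols shared by genes that are not orthologues, stay open and were not tested. Loss of pairs mapping to several near-identical genes also stays open for them. The entry 7SK, which is among them, names the same RNA as RN7SK.

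A second pattern is that most yolk sac and endoderm genes were higher in mouse. Scaling between the species is argued against, since the median log2 fold change of the list stayed at or below -6.28 under each scaling. The presence of yolk sac tissue in the mouse samples would let its genes move together between the mouse libraries. The 17 called members had a median log2 ratio of 0.37 for library 2 over library 1. That lay at percentile 100 of 10000 random lists matched on abundance, and 14 members were higher in library 2. The spread of their ratios (SD 0.32) lay at percentile 73.65 of those lists. The members thus shared a direction, but their ratios were no more alike than those of random lists. A shared direction is compatible with such tissue but not specific to it, as decidual, stromal, macrophage, interferon-stimulated and senescence lists were also higher in mouse library 2. Of the list, 1 gene is also listed among the endothelial markers and 4 of 20 exceeded 10 length-scaled CPM in human placenta; AFP (9480 ± 2084 length-scaled CPM) and APOA1 (4019 ± 1303) were the most abundant in mouse, and a species difference in the placenta itself remains open and untested.

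The last pattern is the higher H2AJ in human. Scaling as its cause cannot be told apart from a species difference, because no spiked-in standard ties the scales together: the log2 fold change was 0.23 (95% interval -0.32 to 0.78) under trophoblast epithelial scaling and 0.44 (0.11 to 0.77) under TMM, the call ending with a smaller fold and a wider error. Relative to the median of all genes it was 0.45 and 0.43. The exonic length assigned to H2AJ cannot be told apart either, because gene-level counts do not show which annotated bases were transcribed. The lowest value over the lengths tried was 0.29 (-0.04 to 0.62), with free bases as length. The highest, 2.82, came with only the human length shortened. Mouse H2AJ shares 141 bases with AC122804.1 and human H2AJ shares 0, so pairs lost over shared bases would lower the mouse count alone. Free bases as length need not correct this in full, since pairs reaching from free into shared bases were also not counted. Such a loss as a cause of the higher H2AJ was not tested.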

How the results depend on the processing

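The length, protein-coding and trophoblast epithelial alternatives were chosen after seeing the data. H2AJ was higher in human under each of 22 alternatives, from 0.23 to 2.82 on the log2 scale, and called in 16, with adjusted p from 2.37e-05 to 1. It was not called against a 2-fold change (0.44), with free bases as length (0.29) or with trophoblast epithelial scaling (0.23), and ranged from 0.32 to 0.52 with a library left out, where the lone sample was assumed to vary like the other group. Against a 2-fold change 3310 genes were higher in human and 3268 in mouse, by a stricter hypothesis, and with total and housekeeping scaling 3295 and 3128 were higher in mouse, through the shift of all genes by the scaling. The share of calls higher in human was 50.2%, but 69.0% with total, 71.3% with housekeeping and 44.3% with trophoblast epithelial scaling. The number of called lists ran from 6 to 9, against 8, and no setting called a list with an estimated correlation. H2AJ made up 13.6 percentage points more of replication-independent H2A in human, the reverse of its share of all H2A (-1.65), because the denominator leaves out replication-dependent genes. With the human coding exon alone as length its share of all H2A also reversed (7.74 points), because a shorter length, given to human alone, raises the length-scaled count. Its rank became top 11.5% and 9.24% in human and 25.5% and 25.3% in mouse by CPM, and 13.2%, 10.01%, 21.1% and 19.8% among matched genes. The top unmatched genes shared 7 of 10 with those by CPM in each species. Single genes reversed in 8 cases. With total scaling, H2AZ2 was at 0.46 and H3-3B at 0.29. With housekeeping scaling, H2AZ1 was at 0.018, H2AZ2 at 0.59 and H3-3B at 0.41. With no length term, H2AZ2 was at 0.93, H3-3B at 0.25 and PCNA at -0.43. For the scalings the shift of all genes is the cause. Without a length term, the ratio of annotated lengths between the species enters the fold change. H2AZ2 has 4749 exonic bases in human and 1633 in mouse, H3-3B 6134 and 2976, and PCNA 1471 and 2400. Part of the shift with total scaling may come from RN7SK and RPPH1, which were counted in mouse only. Besides these, named genes other than HAND1 and TEAD4 lost a call in 11 combinations of gene and setting and gained it in 11. They kept direction and side of the threshold in 2221. Gene lists lost a call in 16 such combinations, gained it in 6 and kept both in 483.

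Same-numbered libraries deviated from their species mean with r = 0.01 across genes, which gave no sign that the replicate numbers pair the libraries. This correlation cannot exclude shared handling that acted on different genes in each species. With the replicate block, H2AJ was at 0.43 (adjusted p 0.0294), 5134 genes were higher in human and 5145 in mouse, and 9 lists were called, the decidual list being added (adjusted p 0.0412). Depth limits genes with few counts, such as CENPA with 30 and 32 pairs in human and MACROH2A2 with 29 and 21.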

Other observations

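The libraries of each species also differed from each other in cell-type lists. In human, library 1 had higher extravillous trophoblast genes (19 of 21 members, median log2 ratio 0.69, percentile 100 of 10000 random lists matched on abundance), hypoxia and glycolysis genes (21 of 23, 0.29, percentile 99.9), trophoblast epithelial genes (17 of 20, 0.32, percentile 99.9), cell cycle genes (22 of 30, 0.23, percentile 99.8) and syncytiotrophoblast genes (15 of 25, 0.26, percentile 99.4). Library 2 had higher erythroid genes (14 of 14, library 1 over 2 at -1.53, percentile 0), interferon-stimulated genes (27 of 27, -0.64, percentile 0), lymphoid genes (11 of 15, -0.44, percentile 0.94) and endothelial genes (12 of 20, -0.09, percentile 2.01). Among unmatched genes, the tachykinin TAC3 stood at 59.9 and 7.34 CPM and the beta-globin HBB at 329 and 2030 CPM in human libraries 1 and 2. In mouse, library 1 had higher mouse trophoblast lineage genes (10 of 10, 0.53, percentile 100) and extravillous trophoblast genes (16 of 21, 0.25, percentile 99.99). Trophoblast epithelial genes, trophoblast transcription factors and transport, steroid and imprinted genes were also higher in mouse library 1, at percentiles from 97.7 to 98.9. Library 2 had higher macrophage (17 of 18, -0.64), stromal (16 of 22, -0.62), decidual (18 of 20, -0.42), interferon-stimulated (23 of 27, -0.29), yolk sac (14 of 20, -0.27) and senescence genes (16 of 25, -0.23), each at percentile 0. The other lists lay between percentiles 13 and 90.6 in human and between 4.74 and 95.9 in mouse. These percentiles describe single libraries and carry no replicate check.

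Some gene families were nearly confined to one species in the tables. Placental cathepsins took 2.55% ± 0.30 of mouse counts, Tpbpa and Tpbpb 2.11% ± 0.41, and Ceacam genes 1.75% ± 0.47 (SD, n = 2), against 0.00316% ± 0.00076 for human CEACAM genes. The beta subunits of chorionic gonadotropin took 0.00595% ± 0.0031 of human counts, a share that leaves out pairs mapping to several of these near-identical copies. The envelope-derived syncytin ERVW-1 stood at 674 ± 8.68 CPM and ERVFRD-1 at 66.5 ± 15.7 CPM in human, and the mouse syncytins SynA and SynB at 4.15 ± 0.16 and 0.33 ± 0.065 CPM (TAC3, ERVW-1, ERVFRD-1, SynA and SynB were chosen after their values were seen). These syncytin values are not length-scaled, leave out pairs mapping to several places and come from genes without a symbol match. They were therefore not compared between the species.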
